A study of Homo sapiens with 16 samples.

How the data were processed

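The samples were 16 snm3C-seq libraries of the WTC11 human iPSC line, 2 biological replicates in each of 8 groups. Groups were taken from the deposited titles and characteristics, which name the cell type, the differentiation (atrial or ventricular), the day and the TBX5 genotype. Per the labels' growth protocol, each replicate was grown in its own culture well. The replicates are thus separate cultures of the same line, and p-values measure the spread between such cultures and their library preparation. For TBX5, the samples named in/+ were taken as heterozygous and those named in/del as null, per the labels, with 1 and 0 unedited copies.

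Each library was deposited as a mapping summary with 1 row per well of a 384-well plate. Per the labels' protocols, cells were fixed with formaldehyde and taken through an in situ 3C digestion and ligation with a commercial kit. The submitters' processing notes name cutadapt 2.10, Bismark 0.20, Bowtie2 2.3, SAMtools 1.9, Picard 3.0.0 and the hg38 genome, without their roles. The authors deposited counts of reads at each processing step, counts of methylated and of all base calls in CG, CH and CCC context, and counts of short-range cis, long-range cis and trans contacts, per the file headers. The same files hold methylation levels, contact ratios and trimming rates, deposited as a fraction, and mapping and duplication rates, deposited as a percent, per the file headers. The headers record no normalization between wells or plates. The distance that separates short from long cis contacts is not given in the sources used here. Total contacts per plate equalled 97.1% to 104% of the deduplicated first reads, so the short-range class cannot be separated from fragments that were never ligated. Any change in the share of such fragments moves all shares of total contacts, and for this reason the shares of long-range cis plus trans contacts are given too.

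A well counted as a cell when it held at least 500000 final reads, an mCCC under 5% and an mCG over 50%. Of 6144 wells, 677 had too few reads and 309 had a high mCCC, some of them both, and 5444 passed. No doublet caller was run, since the files hold no values per gene or region, and no cell was given a type from the data. For each plate, every measure was the mean over its passing cells. mCG, mCH and mCCC were methylated calls over all calls in the context, as a percentage, and contact shares were percentages of all contacts of the cell. The 11 secondary measures were the mCCC level, mCH minus mCCC, the between-cell SD of mCG and of mCH, the ratio of long-range to short-range cis contacts, contacts per mapped read, final reads per cell, the duplication and mapping rates, the number of passing cells and the share of cells within the central 95% range of iPSC cells in both mCG and mCH. Final reads per cell were summarised by the median. A trans share over 80% of long-range cis plus trans contacts was counted as well, at a value chosen after the data had been seen.

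The measures, groups, filter, tests, threshold and most of the alternatives were chosen before the data were examined. Because the files have no gene columns, the rule for named items fixed the 4 primary and 11 secondary measures with no selection on their values. TBX5 is named as the edited gene only, and the edit itself was not checked in the data. The 5 comparisons were cell type stage (12 unedited plates), the atrial course (8), the ventricular course (6), TBX5 dose (6) and lineage at day 6 (4). Each used an exact two-sided permutation test of the covariance between the plate values and the group order, or of the difference in means for 2 groups, over all assignments of plates to groups (13860, 2520, 90, 90 and 6). p-values were adjusted by the Benjamini-Hochberg method over the 4 primary measures of a comparison, and separately over the 11 secondary measures, and a result passed at an adjusted p below 0.05. With long-range cis plus trans contacts as the denominator, the long-range cis and trans shares are complements and give a single test. Its p was adjusted as 1 of 3 measures, with mCG and mCH, a choice made after the data had been seen. Errors are SDs between plates, and pooled SDs are taken within the groups of a comparison. The stage comparison holds every plate of both courses, and the 2 courses share the iPSC plates. These comparisons are therefore not independent of each other. The stage tests count every plate as independent, although precursors and cardiomyocytes each hold several groups of 2 replicate plates. Plates of a group can be alike, so the p-values of all stage tests may be too small. Cells were never used as replicates. Shares of cells of a single plate carry exact Clopper-Pearson 95% intervals, which cover counting error only.

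The test was tested on simulated data. With no difference, 5.4% of 500 simulations of the stage comparison and 4.8% of those of the TBX5 dose comparison gave an unadjusted p below 0.05. With a shift of 1 SD per step, 62.6% and 26.4% did, and with 2 SDs 99.8% and 77.2%. Simulated plates were independent, with no value shared within a group. The stage rates therefore need not hold for the real stage plates, which come in groups of 2. The 120 pairs of files were compared well by well, and in no pair did any well hold equal final reads, so no library was counted more than once.

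Alternatives were no cell filter, at least 1000000 reads, mCCC under 2%, the median over cells, counts pooled over cells, correction of each cell for its mCCC, a common window of reads, a test without group order, a replicate block, each plate left out in turn, the denominator of long-range cis plus trans contacts, and a 90% iPSC range. Leaving out the day 20 plates and leaving out cells over 80% trans were added after the data had been seen. The columns for the lambda control held no calls in any of the wells and were not used. Sequences, coordinates and values at single genes were not analysed here. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.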

Results

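Single-nucleus methyl-3C sequencing (snm3C-seq), which reads DNA methylation and chromosome contacts from the same nucleus, was applied to WTC11, an established human induced pluripotent stem cell (iPSC) line, and to heart muscle cells made from it. The 16 samples formed 8 groups of 2 biological replicates. Each replicate was a separate culture well and was read out on 1 plate of 384 wells. The unedited line was sampled as iPSC at day 0, along an atrial differentiation at days 6, 20 and 45, and along a ventricular differentiation at days 6 and 23. Cells at day 6 are labelled cardiac precursors, and cells from day 20 on are labelled cardiomyocytes. At day 20 of the atrial differentiation, 2 further genotypes were sampled, heterozygous and null for TBX5, a cardiac T-box transcription factor linked to inherited heart disease.

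The measurements were genome-wide summaries per cell. CpG methylation (mCG) is the usual form of DNA methylation in human cells, and methylation at other cytosines (mCH) is found mainly in pluripotent cells and neurons. Methylation called at CCC trinucleotides (mCCC) served as the background of the chemical conversion. Contacts were divided into short-range cis and long-range cis (both ends on the same chromosome) and trans (ends on different chromosomes). No value for a gene or a region entered the comparisons. Of 6144 wells, 5444 (88.6%) passed the cell filter, with 282 to 360 cells per plate. The median cell of a plate held 602096 to 1919730 final reads, 622786 to 1699950 CpG calls and 305249 to 960286 contacts, and covered 1.61% to 4.31% of the genome.

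The first comparison asked how methylation and contacts differ between iPSC, cardiac precursors and cardiomyocytes of the unedited line. Contacts between different chromosomes were less frequent in cardiomyocytes than in iPSC or precursors. The trans share of all contacts was 17.2% ± 0.545 (SD, n = 2) in iPSC, 15.4% ± 1.98 (SD, n = 4) in cardiac precursors and 11.3% ± 2.19 (SD, n = 6) in cardiomyocytes. Among long-range cis and trans contacts alone, the trans share went from 51.9% ± 1.96 (SD, n = 2) in iPSC through 49.1% ± 4.04 (SD, n = 4) in precursors to 38.1% ± 3.64 (SD, n = 6) in cardiomyocytes. Of the precursors, only the ventricular ones lay below iPSC in this share, at 45.9% ± 1.58 against 52.4% ± 1.98 in atrial ones (SD, n = 2 each). From iPSC to cardiomyocytes the trans share of all contacts fell by 5.89 percentage points (pooled SD 1.14), and the trend passed the test (exact two-sided permutation p = 0.00180, adjusted p = 0.00722). The test counts plates as independent, but plates of a group were closer to each other (pooled SD 1.14) than cardiomyocyte plates were (SD 2.19). This p and those of the other stage tests may therefore be too small.

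The long-range cis share, the share of contacts that join distant parts of a chromosome, was 16.1% ± 0.763 (SD, n = 2) in iPSC, 15.9% ± 1.26 (SD, n = 4) in precursors and 19.0% ± 5.81 (SD, n = 6) in cardiomyocytes, and did not pass (exact permutation p = 0.302, adjusted p = 0.403). The wide spread among cardiomyocytes came with a technical split of the plates. In the 6 day 20 plates, 96.9% to 97.9% of reads were left after trimming and 40.3% to 55.9% of mapped reads were duplicates. In the other 10 plates these shares were 42.5% to 87.7% and 11.1% to 33.3%. Short-range cis contacts made up 75.8% to 80.6% of contacts in the day 20 plates and 62.0% to 71.0% in the others. Because this set holds all day 20 plates and no other, the set and the day cannot be told apart.

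Without the day 20 plates, an alternative added after the data had been seen, cardiomyocytes held 22.6% ± 1.71 (SD, n = 4) long-range cis contacts against 16.1% in iPSC. This increase of 6.55 percentage points passed (exact permutation p = 0.00603, adjusted p = 0.0121). The trans share in the same plates fell by 4.51 percentage points from iPSC to cardiomyocytes and passed as well (exact permutation p = 0.00381, adjusted p = 0.0121). With trans contacts counted among long-range contacts only, the share fell by 13.7 points over all 12 plates (adjusted exact permutation p = 0.00281) and by 15.9 points without day 20 (adjusted exact permutation p = 0.00762).

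No difference in plate mean CpG methylation between stages passed after adjustment, but the plate median did without the day 20 plates. Mean mCG was 78.4% ± 0.551 (SD, n = 2) in iPSC, 74.4% ± 0.527 (SD, n = 4) in cardiac precursors and 76.2% ± 1.99 (SD, n = 6) in cardiomyocytes. The cardiomyocyte groups ranged from 74.1% in atrial cells at day 45, below both precursor groups, to 78.5% in unedited atrial cells at day 20, close to iPSC. Both precursor lineages lay below iPSC with no overlap between plates, atrial by a difference of -3.87 and ventricular by -4.21 percentage points. The test against stage order did not pass (exact permutation p = 0.518, adjusted p = 0.518), nor did it without the day 20 plates, where cardiomyocytes averaged 75.1% ± 1.11 (exact permutation p = 0.0613, adjusted p = 0.0817). Without day 20, the median over cells was 79.4% in iPSC, 74.8% in precursors and 75.1% in cardiomyocytes (exact permutation p = 0.0229, adjusted p = 0.04 over 7 per-cell measures chosen after the data had been seen). The 90th percentile was 81.9%, 77.5% and 77.5% in that order (exact permutation p = 0.0114, adjusted p = 0.0267). Over all 12 plates neither passed, with adjusted exact permutation p-values of 0.456 and 0.588. A test of any difference in mean mCG between the 3 stages gave an exact permutation p of 0.0388 and an adjusted p of 0.0776.

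Methylation outside CpG was also highest in iPSC once the conversion background was removed. The excess of mCH over mCCC was 1.26 ± 0.0355 percentage points (SD, n = 2) in iPSC, 0.800 ± 0.153 (SD, n = 4) in precursors and 0.596 ± 0.273 (SD, n = 6) in cardiomyocytes. Its exact permutation p was 0.00455, and the p adjusted over 11 secondary measures was 0.05, at but not below the threshold. Without the day 20 plates the excess in cardiomyocytes was 0.769 ± 0.0687 (SD, n = 4), and the decrease passed (exact permutation p = 0.00952, adjusted p = 0.0372). The uncorrected mCH level was 2.61% in iPSC and 1.97% in cardiomyocytes, a difference of -0.642 percentage points with an exact permutation p of 0.0302 and an adjusted p of 0.0603. With no cell filter the difference was -0.119 points (adjusted exact permutation p = 0.990). The decrease passed after each cell was corrected for its mCCC, where the level fell by 0.676 points (adjusted exact permutation p = 0.00909).

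Cells of a plate differed less from each other in mCG at later stages when day 20 was left out. The between-cell SD of mCG was 3.23 ± 0.0521 percentage points (SD, n = 2) in iPSC, 2.67 ± 0.220 (SD, n = 4) in precursors and 1.96 ± 0.0858 (SD, n = 4) in cardiomyocytes of days 23 and 45 (exact permutation p = 0.000317, adjusted p = 0.00349). With the day 20 plates, whose unedited cells had a between-cell SD of 2.94, the cardiomyocyte value was 2.28 and the adjusted exact permutation p was 0.0790. Over these plates the difference from iPSC to cardiomyocytes was -0.949. With no cell filter it was -1.99 (pooled SD 0.822, adjusted exact permutation p = 0.441). The share of cells within the central 95% range of iPSC in both mCG and mCH was 90.3% ± 2.95 (SD, n = 2) in iPSC, 69.5% ± 13.3 (SD, n = 4) in precursors and 56.9% ± 34.3 (SD, n = 6) in cardiomyocytes, and did not pass (adjusted exact permutation p = 0.487). Without day 20 it was 77.3% ± 16.0 (SD, n = 4) in cardiomyocytes, above precursors (adjusted exact permutation p = 0.798). Because the range was set on these same iPSC cells, their own share is high by construction. The mCH used for it was not corrected for mCCC.

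**Figure D1:**
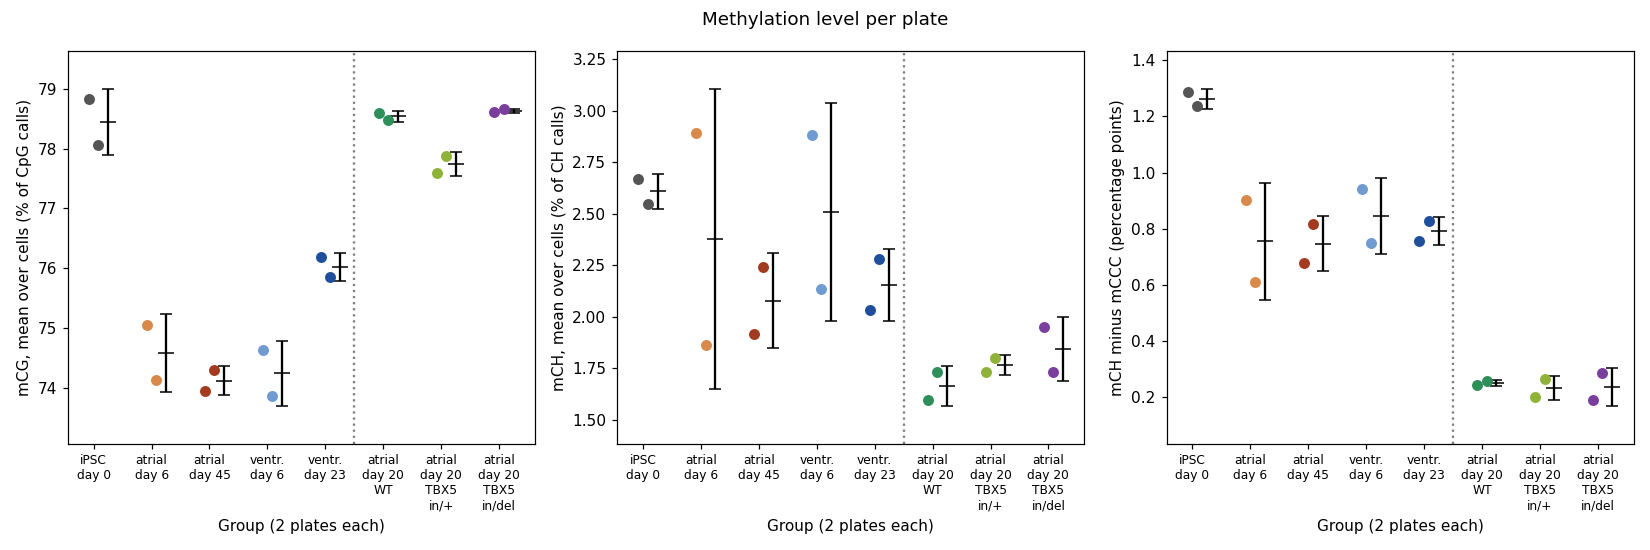
Each point is the mean over the cells of 1 plate, for mCG (percent of CpG calls), mCH (percent of CH calls) and the excess of mCH over mCCC (percentage points), in the 8 groups; horizontal bars are the mean of 2 plates and vertical bars ± 1 SD. The iPSC plates lie at 78.1% and 78.8% mCG, above all day 6 plates (73.9% to 75.04%), and the day 20 plates, right of the dotted line, form the separate technical set and lie lowest in the mCH excess (0.189 to 0.285).

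Along the atrial differentiation the question was how the same measures move from iPSC to atrial cardiomyocytes of day 45. Both plates of atrial cells at day 45 had fewer trans and more long-range cis contacts than any iPSC or atrial precursor plate. The trans share of all contacts was 16.5% ± 2.41 at day 6 and 12.3% ± 0.676 at day 45 (SD, n = 2 each), and the long-range cis share was 14.9% ± 1.01 at day 6 and 22.6% ± 0.734 at day 45. Unedited day 20 plates fell outside this order, with 8.58% ± 0.209 trans and 11.7% ± 0.346 long-range cis contacts. Among long-range cis and trans contacts alone, the trans share was 51.9% at day 0, 52.4% ± 1.98 at day 6, 42.5% ± 1.26 at day 20 and 35.2% ± 0.531 at day 45 (SD, n = 2 each).

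With this last denominator the decrease of 16.6 percentage points along the atrial course passed (exact permutation p = 0.00397, adjusted p = 0.0119, 8 plates). Without the day 20 plates the same decrease did not pass (exact permutation p = 0.0556, adjusted p = 0.133, 6 plates). The smallest exact p with these 6 plates is 0.0222, and a measure that reaches it alone among 3 cannot pass. None of the 4 primary measures passed over the 8 plates. Their adjusted exact permutation p-values were 0.241 for the trans share and 0.258 for each of the long-range cis share, mCG and mCH. Without the day 20 plates, 6 plates were left, and the long-range cis and trans shares had exact permutation p-values of 0.0556 and 0.0444, with an adjusted p of 0.111 for both. Mean mCG was 74.6% ± 0.651 at day 6, 78.5% ± 0.0881 at day 20 and 74.1% ± 0.241 at day 45 (SD, n = 2 each), so that the day 20 level was close to that of iPSC.

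Along the ventricular differentiation, which includes no day 20 plate, contacts moved in stage order. Its plates still differed in the reads left after trimming (47.2% to 87.7%) and in duplicates (15.1% to 33.3%). The long-range cis share rose from 16.1% ± 0.763 in iPSC to 16.8% ± 0.175 at day 6 and 22.6% ± 2.87 at day 23 (SD, n = 2 each). The trans share fell from 17.2% ± 0.545 to 14.3% ± 1.06 and 13.1% ± 0.328 at the same times. Both passed with the smallest p that 6 plates allow (exact permutation p = 0.0222, adjusted p = 0.0444). Mean mCG was 74.2% ± 0.543 at day 6 and 76.0% ± 0.235 at day 23 (SD, n = 2 each), higher at day 23 by 1.77 percentage points. The trend of mCG from day 0 did not pass (exact permutation p = 0.244, adjusted p = 0.244), nor did that of mCH, which was 2.61% in iPSC and 2.16% at day 23 (exact permutation p = 0.222, adjusted p = 0.244).

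Both ventricular contact calls rest on that smallest p. With the median over cells, with contacts pooled over cells or with no cell filter, the direction stayed and the adjusted exact permutation p became 0.0889.

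**Figure D2:**
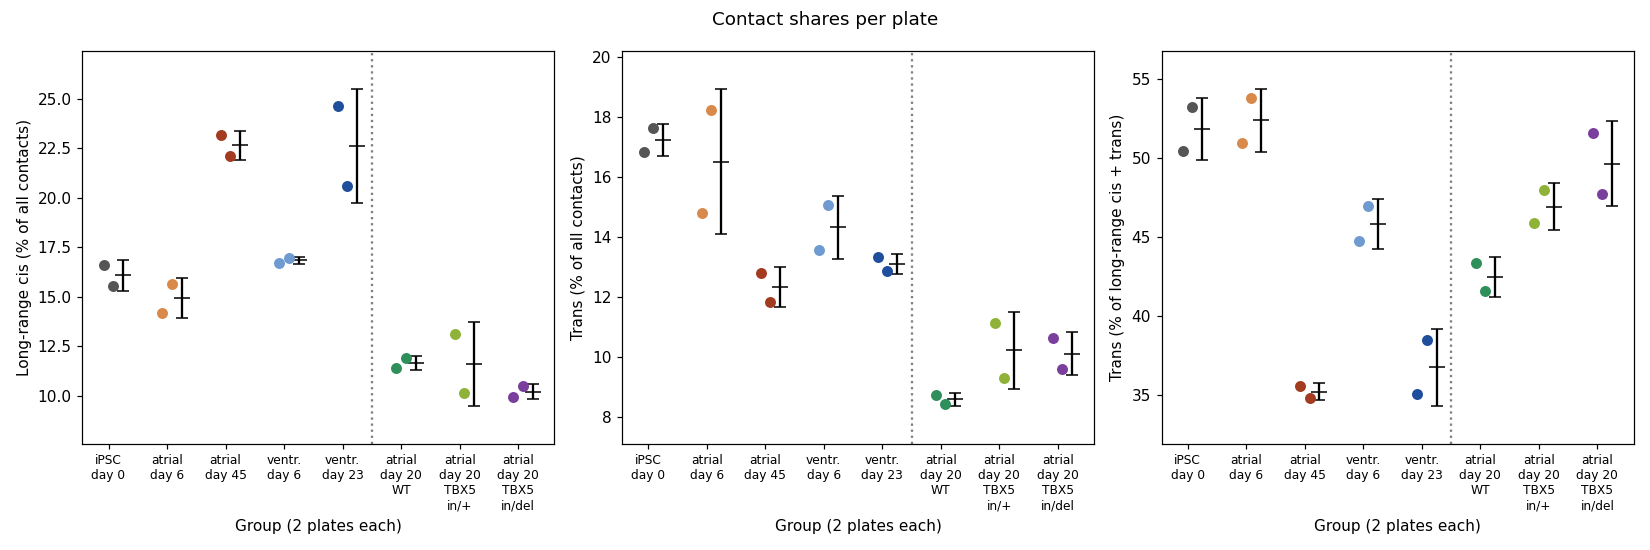
Each point is the mean over the cells of 1 plate for the long-range cis share and the trans share (percent of all contacts) and for the trans share of long-range cis plus trans contacts (percent), in the 8 groups; horizontal bars are the mean of 2 plates and vertical bars ± 1 SD, and the axes do not start at 0. In the last panel, day 45 atrial (34.8% and 35.6%) and day 23 ventricular plates (35.0% and 38.5%) lie below the iPSC plates (50.5% and 53.2%), and right of the dotted line the TBX5 null plates (47.7% and 51.6%) lie above the unedited ones (41.6% and 43.4%).

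The genotype series asked whether the number of unedited TBX5 copies changes methylation or folding of the genome in day 20 atrial cardiomyocytes. The sample descriptions name no separate clones of a genotype. TBX5 dose therefore cannot be told apart from other differences between the edited and unedited lines, and the p-values cover only the spread between replicate cultures. None of the 4 primary measures passed. The trans share of all contacts was 8.58% ± 0.209 in unedited cells, 10.2% ± 1.28 in TBX5 heterozygous cells and 10.1% ± 0.728 in TBX5 null cells (SD, n = 2 each), with an exact permutation p of 0.178 and an adjusted p of 0.356. The long-range cis share was 11.7% ± 0.346, 11.6% ± 2.12 and 10.2% ± 0.376 in the same order (exact permutation p = 0.267, adjusted p = 0.356). Taken among long-range cis and trans contacts, the trans share was 42.5% ± 1.26 in unedited, 46.9% ± 1.48 in heterozygous and 49.6% ± 2.70 in null cells (SD, n = 2 each). Here null and unedited plates differed by 7.19 percentage points, or 3.74 pooled SDs, with an exact permutation p of 0.0444 that did not pass after adjustment (adjusted p = 0.133).

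No trend of mean mCG with TBX5 dose was detected. Mean mCG was 78.5% ± 0.0881 in unedited, 77.7% ± 0.200 in heterozygous and 78.6% ± 0.0371 in null cells (SD, n = 2 each; exact permutation p = 0.889, adjusted p = 0.889). Mean mCH was 1.67% ± 0.0964, 1.77% ± 0.0481 and 1.84% ± 0.155 (exact permutation p = 0.133, adjusted p = 0.356), and the excess over mCCC was 0.250, 0.232 and 0.237 percentage points. Null cells differed more from each other in mCG, with a between-cell SD of 3.72 ± 0.119 against 2.94 ± 0.0157 in unedited and 2.94 ± 0.105 in heterozygous cells (SD, n = 2 each). This trend did not pass (exact permutation p = 0.0889, adjusted p = 0.407 over 11 secondary measures). With 6 plates the smallest exact p was 0.0222. A measure that reaches it alone cannot pass after adjustment over 4 primary or 11 secondary measures, whatever its effect. Among simulated trends in 6 plates, 26.4% reached an unadjusted p below 0.05 at a shift of 1 SD per copy and 77.2% at 2 SDs. These shares do not apply to adjusted calls.

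**Figure D3:**
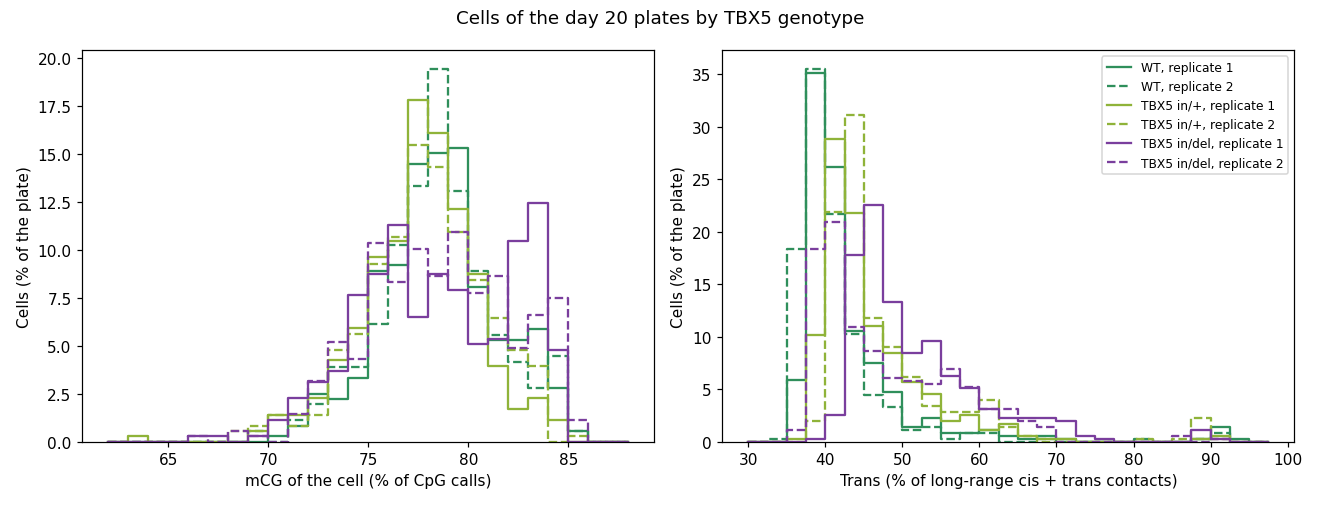
Histograms of the cells of the 6 day 20 plates (percent of the cells of a plate), by mCG of the cell (percent of CpG calls) and by the trans share of its long-range cis plus trans contacts (percent); each line is 1 plate, coloured by TBX5 genotype, solid for replicate 1 and dashed for replicate 2. The null plates spread over a wider range of mCG, with between-cell SDs of 3.64 and 3.81 against 2.93 and 2.95 in the unedited plates.

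Atrial and ventricular precursors, compared at day 6 as the only day shared by both lineages, differed in mean mCG by less than the spread between plates, at 74.6% ± 0.651 and 74.2% ± 0.543 (SD, n = 2 each). Part of this spread ran along the replicate number. Atrial and ventricular mCG were 75.04% and 74.62% in replicate 1, and 74.12% and 73.86% in replicate 2. Within each number the ventricular plate was thus the lower, but whether the numbers mark true pairs is not known. Ventricular precursors had a lower trans share of long-range cis plus trans contacts, 45.9% ± 1.58 against 52.4% ± 1.98 in atrial precursors, a difference of -6.52 percentage points with no overlap between plates. Long-range cis contacts made up 16.8% ± 0.175 of all contacts in ventricular and 14.9% ± 1.01 in atrial precursors. The trans share was 14.3% ± 1.06 and 16.5% ± 2.41 in that order, and mCH was 2.51% ± 0.528 and 2.38% ± 0.728. With 2 plates against 2, the smallest exact permutation p is 0.333, so that none of these differences can pass. The later cardiomyocytes were sampled on different days. At day 23, ventricular cells had a mean mCG of 76.0% ± 0.235 and, at day 45, atrial cells had 74.1% ± 0.241 (SD, n = 2 each), while their long-range cis shares were both 22.6%.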

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

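A single result was flagged between genotypes, because its heterozygous and null effects had opposite signs, and no test was chosen for it after it was seen. It was not the largest difference between genotypes. The between-cell SD of mCG differed by 8.50 pooled SDs between null and unedited plates, also without passing after adjustment. In day 20 atrial cardiomyocytes, both TBX5 heterozygous plates had lower mean mCG (77.6% and 77.9%) than both unedited plates (78.5% and 78.6%), while both null plates (78.6% and 78.7%) lay above them. The heterozygous plates thus differed from unedited ones by -0.803 percentage points and the null plates by 0.0903. The null effect was near 0 and moved with plates and processing. It was 0.153 without unedited replicate 1 and 0.0280 without unedited replicate 2, 0.395 in a common window of reads, 0.237 with no cell filter, 0.169 with at least 1000000 reads and 0.0401 with mCCC under 2%. The gap between these opposite effects was 0.894 percentage points. As a difference between effects it was not tested; it equals the difference between null and heterozygous plates, whose exact permutation p of 0.333 is the smallest that 2 plates against 2 allow. The test of any difference between the 3 genotypes gave an exact permutation p of 0.0667, the smallest it can give, and an adjusted p of 0.267.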

How the results depend on the processing

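The alternatives without day 20 plates, without cells over 80% trans and with complements counted once were chosen after the results were seen. Of 320 alternative values of the primary measures, 282 kept their direction and side of the threshold, 24 kept the direction but no longer passed, 7 newly passed and 7 changed direction; of 169 for secondary measures, 157 kept both, 9 newly passed and 3 changed direction. The fall of the trans share with stage passed under every alternative run, none of which took whole groups as the unit. The fall of mCH with stage newly passed with mCCC under 2% (-0.648, adjusted exact p = 0.0208) and after conversion correction (-0.676, 0.00909), but with no cell filter it was -0.119 (adjusted exact p = 0.990). Leaving out 1 plate gave -0.705 to -0.568, and without the atrial day 6 replicate 2 it passed (-0.642, adjusted exact p = 0.0398). The rise of the long-range cis share with stage passed without day 20 (6.55). With the long-range plus trans denominator, long-range cis and trans are complements, so that 13.7 by stage restates the fall in trans, and the atrial 16.6 and -16.6 are a single result that enters the 7 as 2 values. Counted once, it passed by stage (adjusted exact p = 0.00281) and in the atrial course (0.0119), but not in the ventricular course (0.0667), where it passed when counted as 2 measures (0.0444). The ventricular exact p of 0.0222 is the smallest that 6 plates allow. A measure that reaches it alone among 3 cannot pass. Both ventricular calls were lost at adjusted exact p = 0.0889 with no cell filter (6.16 for long-range cis, -4.13 for trans), the median (6.10, -4.15), pooling (6.29, -3.87) and without cells over 80% trans (5.84, -3.57), where at least 1 of both measures no longer had the smallest p. A test without group order (6.53, -4.12) cannot pass here: its exact p of 0.0667 is the smallest that 6 plates allow. Leaving out any 1 of the 6 plates gave 4.50 to 8.56 and -4.51 to -3.74 (adjusted exact p 0.0667 to 0.267), where the smallest p is 0.0333 without a day 0 or day 23 plate and 0.0667 without a day 6 plate. Direction changed for mCH with no cell filter in the atrial course (0.939) and at day 6 (-0.0293), for mCH by TBX5 dose after conversion correction (-0.0129), for its excess over mCCC with mCCC under 2% (0.00950), and when 1 plate was left out for that excess (-0.0607 to 0.0350, positive without null replicate 1), for mCG at day 6 (-0.801 to 0.120, positive without atrial replicate 1 or ventricular replicate 2), for mCH at day 6 (-0.383 to 0.647, negative without atrial replicate 2 or ventricular replicate 1) and for the ventricular iPSC-range share (-21.1 to 2.18, positive without day 23 replicate 1). The cause of these changes was not tested. With a replicate block, the ventricular values (6.53, -4.12) had an exact p of 0.0556, the smallest that block allows. Among the other results given this block, all over the full plates of a comparison, no call changed. Whether plates with the same replicate number share a batch cannot be told here, as each r below rests on 4 measures. Plates with the same number deviated together (r over 0.1) in 5 of 15 pairs of groups by stage, 1 of 6 atrial, 2 of 3 ventricular, 0 of 3 by TBX5 dose and 1 of 1 at day 6 (r = 0.977). At day 6, atrial and ventricular mCH were 2.89% and 2.88% in replicate 1, and 1.86% and 2.14% in replicate 2. Their mCCC was 1.99% and 1.94% in replicate 1, and 1.25% and 1.39% in replicate 2. At least 1000000 reads and a common window of reads could be applied only to TBX5 dose, because elsewhere a plate kept fewer than 10 cells.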

Other observations

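The tests on the short-range class and on the technical set, the 80% limit on the trans share and the 7 per-cell measures were chosen after the results were seen. A distinct minority of cells had nearly only trans contacts at long range. Cells with over 80% trans among long-range cis plus trans contacts made up 5.16% (Clopper-Pearson 95% interval 3.09 to 8.03) and 4.96% (2.91 to 7.82) of the iPSC plates. They were absent among 357 and 334 ventricular cells of day 23 (Clopper-Pearson upper bounds 1.03% and 1.10%). Precursor and cardiomyocyte plates overlapped. Atrial replicate 1 at day 6 held 0.923% (Clopper-Pearson 95% interval 0.191 to 2.67) of such cells. Atrial replicate 2 at day 45 held 1.75% (0.646 to 3.78), and unedited replicate 1 at day 20 held 1.95% (0.787 to 3.98). Mean shares were 5.06% in iPSC, 3.41% in precursors and 0.849% in unedited cardiomyocytes (exact permutation p = 0.00166, adjusted p = 0.00581 over 7 per-cell measures), and 0.439% in cardiomyocytes without day 20 (exact permutation p = 0.00317, adjusted p = 0.0111). Their median mCG in the iPSC plates was 75.8% and 76.0%, against 79.9% and 79.1% in the other cells. This direction did not hold in every plate, as in ventricular replicate 1 at day 6 (76.3% against 74.97%) and in both TBX5 heterozygous plates (78.2% against 77.8%, and 78.4% against 77.9%). Few cells were intermediate, with 1 cell of all 16 plates having a trans share between 75% and 80%.

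In iPSC, cells with more reads had lower mCG. The rank correlation of mCG with final reads across the cells of a plate was -0.271 and -0.350 in the iPSC plates, averaged -0.0659 in precursors and 0.0654 in unedited cardiomyocytes. This trend over plates had an exact permutation p of 0.000361 (adjusted p = 0.00253), and without day 20 an exact permutation p of 0.00127 (adjusted p = 0.00889). In the same iPSC plates mCG also followed the conversion background most closely, with rank correlations of mCG and mCCC of 0.402 and 0.384, against -0.0461 to 0.253 in the other plates. Cells are not replicates, so the plates were the units of the test, with the plates of a group counted as independent.

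No per-cell trend with TBX5 dose passed after adjustment over 7 measures. The smallest exact p with these 6 plates is 0.0222, and a measure that reaches it alone among 7 cannot pass, whatever its effect. The 10th percentile of mCG was at this smallest p, so its adjusted p does not tell whether a trend exists. Across cells of a plate, mCG and the trans share of long-range cis plus trans contacts had a mean rank correlation of 0.230 in unedited, 0.217 in heterozygous and -0.113 in null plates (exact permutation p = 0.0667, adjusted p = 0.156). The 10th percentile of mCG was 74.9%, 74.0% and 73.7% in that order (exact permutation p = 0.0222, adjusted p = 0.156), and the 90th was 82.6%, 81.3% and 83.7% (exact permutation p = 0.422, adjusted p = 0.591).

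The higher trans share among long-range contacts in TBX5 null plates, 7.19 percentage points above unedited plates, was set against 3 technical explanations. Cells over 80% trans were no more frequent in null (1.14%) than in unedited plates (1.67%), so that they cannot account for the excess, which was 7.55 without them (pooled SD 1.67). In a common window of reads, with at least 15 cells per plate, the difference was 6.96 (pooled SD 1.67), and with every plate weighted to the mCG deciles of the unedited cells it was 7.81 (pooled SD 2.13), which argues against depth or a shift in mCG make-up as the whole cause. Other differences in plate preparation remain open. Duplication was 54.0% and 47.2% in heterozygous and 55.9% and 41.0% in null plates, against 40.3% in both unedited plates. In that order the trans shares of the edited plates were 45.9%, 48.0%, 51.6% and 47.7%, against 43.4% and 41.6% in unedited plates. All edited plates thus lay above both unedited plates in both measures. Between replicates, higher duplication went with a lower trans share in heterozygous plates and with a higher one in null plates. A hypothesis that fewer TBX5 copies may raise the trans share, by altered folding or by another mixture of cells, was not tested further, and the trend itself did not pass after adjustment. Such an effect could not be told apart from other differences between the edited and unedited lines.

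The wider mCG spread among TBX5 null cells, an SD 0.780 above that of unedited cells, was set against 3 others. Binomial counting noise of the CpG calls amounted to at most 0.987% of the observed SD in the null plates. After correction of each cell for its mCCC the difference was 0.798 (pooled SD 0.0910), and without cells over 80% trans it was 0.771 (pooled SD 0.0880). These values argue against counting noise, incomplete conversion and near-random cells as the whole cause. Whether a more mixed cell population could account for it is a hypothesis left untested, because the files hold no marker to type cells, and the trend did not pass after adjustment.

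Unedited day 20 plates fell outside the atrial time order in long-range cis share, mCG and mCH excess. Left out of the denominator, the short-range class no longer hid an order: the long-range cis share of long-range cis plus trans contacts was 57.5% at day 20, between 47.6% at day 6 and 64.8% at day 45. This is consistent with dilution by short-range or unligated fragments for the contact shares. For mCG and the mCH excess, a library or processing difference cannot be told apart from day 20 itself, since at least 96.9% of reads were left after trimming in every day 20 plate against at most 87.7% in the other plates, and no plate of another day shares that set. A true change of methylation at day 20 therefore stays open too.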
